A study of Mus musculus with 11 samples.

How the data were processed

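The series holds 11 Affymetrix mouse whole-transcript arrays of liver RNA from male mice: 3 wild-type, 3 Nemo KO, 2 Nemo/TRAIL dKO and 3 Nemo/TNFR1 dKO. Samples were grouped by the genotype in their labels. The array names carry a code that WT and Nemo KO share and that differs in each double knockout, and what it marks is not given in the sources used here. If it marks a batch, that batch is confounded with genotype for both double knockouts. The array numbers follow genotype too: 1 to 3 in WT, 4 to 6 in Nemo KO, 7 and 9 in Nemo/TRAIL dKO and 10 to 12 in Nemo/TNFR1 dKO. An effect of array order would thus be confounded with genotype in every comparison, Nemo KO against WT included. Why the numbers skip from 7 to 9 is not given in the sources used here. The deposited table holds log2 expression values of 35556 probe sets, made by the authors with RMA according to their processing notes. The version of RMA is not given in the sources used here. No further normalization was applied. Of the probe sets 21789 had exactly 1 gene symbol (19938 distinct genes), 1621 had several and 12146 had no gene name in the annotation used. Of the single-symbol probe sets 21698 were matched in the RefSeq table for GRCm38, which was used only for names and for which genes are neighbours.

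The comparisons, tests, gene lists and naming rule, and the alternatives listed below, were chosen before the data were examined. With R 4.3.3 and limma 3.58.1, a linear model with 1 mean per group was fitted to all 11 arrays and all probe sets, with default empirical Bayes moderation (residual degrees of freedom 7, prior 2.51). The p-values are two-sided and were adjusted by Benjamini-Hochberg within each comparison, and a probe set was called at an adjusted p below 0.05 without a fold threshold. The p-values measure only the spread between these samples, and the number of arrays limits the precision. The median standard error of a log2 difference was 0.102 between groups of 3 and 0.114 against the group of 2. The 6 comparisons were each Nemo-deficient genotype against WT, each double knockout against Nemo KO, and both double knockouts against each other. The last is also the test of whether the added knockouts differ in their effect.

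A total of 30 gene lists with 695 entries was written from general knowledge. Of these entries 623 had a single-gene probe set and 72 had none, and a list needed 5 measured members, so that the erythroid markers (4 measured) were not tested. The 29 tested lists covered cell division, liver cell types, immune cells, signalling, metabolism, stress responses, the circadian clock and pancreatic acinar cells. Each was tested with camera of limma (preset correlation between genes 0.01, 1 probe set per gene, the one with the highest mean), two-sided and adjusted over the lists. Camera with a correlation estimated per list and the self-contained test fry were run beside it. Members called "adjusted over the list alone" had their p adjusted among the members of that list.

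Genes were named by a fixed rule. It names the 3 targeted genes in each comparison. For Nemo KO against WT and the comparisons among Nemo-deficient genotypes it names the 8 genes up and the 8 down with the largest log2 difference among called single-symbol probe sets whose groups do not overlap, without predicted gene models. For each list that passed or had at least 3 called members it names up to 3 called members with the largest differences, or else the member with the largest difference as a value only. The probe sets 10421186 and 10344087 and the 4933409K07Rik family fall outside this rule and were named after their values were seen. The same holds for genes named only as members of groups of neighbouring genes, and for Cyp2c39 in Nemo/TRAIL dKO against Nemo KO.

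The signature score of an array is the mean of the probe sets called up minus the mean of those called down in a fit of the 2 groups that chose them, scaled to 0 in WT and 1 in Nemo KO. It was compared by two-sided exact permutation, where the smallest p is 0.1. Overlaps between comparisons that share arrays were set against 100 simulations with shared controls and against independent lists. Shares of called genes near the targeted genes were compared by Fisher's exact test with a window of 10 Mb, and, after the results were seen, pairs of neighbouring genes were counted against 10000 random gene sets.

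The alternatives were a variance trend, robust moderation, quantile normalization, median centring, filters at the 25th percentile and at the median of the mean signal, single-symbol probe sets only, only the 2 groups compared, array weights, a replicate block, a fold of at least 1.5, an adjusted p below 0.01, each array left out in turn, windows of 5 and 20 Mb, and signatures of 100 probe sets per direction. The model was tested on simulated data with the same group sizes and 200 changed probe sets. In Nemo KO against WT it found 59.7% of those changed 1.5-fold, 86.6% of those changed 2-fold and 98.5% of those changed 4-fold, with 7 false calls. Raw image files were not used here.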

Results

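The study measured gene expression in whole liver RNA of male mice aged 8 to 9 weeks and kept on chow. Each of 11 RNA samples was run on its own Affymetrix mouse whole-transcript array, which gave a log2 expression value for each of 35556 probe sets. There were 3 wild-type samples (WT), 3 samples from mice that lack Nemo in hepatocytes (Nemo KO), 2 samples from mice that in addition lack TRAIL in every cell (Nemo/TRAIL dKO) and 3 samples from mice that in addition lack TNFR1 in every cell (Nemo/TNFR1 dKO). Nemo, the product of Ikbkg, is the regulatory subunit of the IκB kinase complex. TRAIL (Tnfsf10) is a death ligand, and TNFR1 (Tnfrsf1a) is a receptor for tumour necrosis factor. The number of arrays limits the precision. WT replicate 3 stood apart from the other arrays in pancreatic acinar markers: the mean of the 10 measured markers lay 3.5 log2 units above the WT mean in this array, and between -2.07 and -1.67 in the other arrays.

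The targeted genes were first compared in every group. A probe set outside the deleted part of a gene checks nothing, and which part was deleted is not given in the sources used here. Ikbkg measured 8.66 ± 0.07 log2 units in WT (SD, n = 3), 8.42 ± 0.12 in Nemo KO (n = 3), 8.25 ± 0.05 in Nemo/TRAIL dKO (n = 2) and 8.21 ± 0.10 in Nemo/TNFR1 dKO (n = 3). Against WT it fell in Nemo/TNFR1 dKO (-0.45 ± 0.08 SE, adjusted p = 0.00818) and in Nemo/TRAIL dKO (-0.41 ± 0.09 SE, adjusted p = 0.0239). In Nemo KO its difference of -0.24 ± 0.08 SE did not pass the test (adjusted p = 0.106). Tnfsf10 measured 6.82 ± 0.27 in WT, 6.54 ± 0.30 in Nemo KO, 6.17 ± 0.09 in Nemo/TRAIL dKO and 6.66 ± 0.15 in Nemo/TNFR1 dKO. Its difference between Nemo/TRAIL dKO and WT was -0.65 ± 0.19 SE (adjusted p = 0.0749), and against Nemo KO it was -0.37 ± 0.19 SE (adjusted p = 1). Tnfrsf1a measured 9.99 ± 0.09 in WT, 10.33 ± 0.13 in Nemo KO, 10.41 ± 0.03 in Nemo/TRAIL dKO and 10.06 ± 0.12 in Nemo/TNFR1 dKO. Against WT it rose in Nemo KO (0.35 ± 0.09 SE, adjusted p = 0.0401) and in Nemo/TRAIL dKO (0.43 ± 0.10 SE, adjusted p = 0.0314), and its difference between Nemo/TNFR1 dKO and Nemo KO was -0.27 ± 0.09 SE (adjusted p = 0.586). With only the 2 groups compared in the fit, Tnfrsf1a did not pass in Nemo KO (adjusted p = 0.0745) or Nemo/TRAIL dKO (adjusted p = 0.0759). Ikbkg then passed in Nemo/TNFR1 dKO (adjusted p = 0.0332) and not in Nemo/TRAIL dKO (adjusted p = 0.0711). The call of Tnfrsf1a in Nemo KO held in 4 of the 11 fits that left out a single array, with adjusted p up to 0.135. In Nemo/TRAIL dKO, the calls of Tnfrsf1a and Ikbkg each held in 7 of the 11, with adjusted p up to 0.175 and 0.133.

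The comparison of Nemo KO with WT asked what the loss of Nemo in hepatocytes changes in the liver. Among single genes, Ly6d, which encodes a surface antigen, rose by 4.35 ± 0.51 log2 units (SE, n = 3 and 3, adjusted p = 0.00114). Mybl1, a transcription factor of the Myb family, rose by 4.16 ± 0.49, Sprr1a by 3.81 ± 0.30 and D17H6S56E-5 by 3.92 ± 0.39. The macrophage genes Gpnmb (3.38 ± 0.25) and Mmp12 (3.37 ± 0.22) and the cyclins Ccna2 (3.22 ± 0.36) and Ccnb2 (3.15 ± 0.29) followed. The largest falls were those of the steroid dehydrogenase Hsd3b5 (-3.67 ± 0.77), Serpina12 (-2.49 ± 0.39), the citrate transporter Slc13a2 (-2.21 ± 0.19), Sult5a1 (-2.15 ± 0.37), Adgrf1 (-2.07 ± 0.28), Hnf4aos (-1.99 ± 0.27), the cytochrome P450 Cyp2c37 (-1.77 ± 0.23) and Pcp4l1 (-1.54 ± 0.17). In all, 3304 probe sets passed the test, 2161 of them higher and 1143 lower in Nemo KO. At the same time 8825 had an unadjusted p below 0.05 and chance alone would give 1778. Of those that passed, 2666 had exactly 1 gene symbol and stood for 1712 distinct genes that rose and 837 that fell, while 123 had several and 515 no gene name. A total of 1680 of the probe sets that passed changed by at least 1.5-fold. The count was 2869 without WT replicate 3, the array with pancreatic transcripts. It dropped to 1979 without Nemo KO replicate 2 and to 1933 without Nemo KO replicate 3. Of the 72 genes named for this comparison, 55 passed with any single array left out. Of the other 17, Gadd45b, Cyp2b10, Tspan8 and Nkg7 are described below, Btg2, H2-Eb1 and Wee1 lost their calls in 5 of the 11 fits, Bhlhe40 and Cidec in 4, H2-Aa, H2-Ab1 and Hmox1 in 3, Cd5l, Hal and Hsd3b5 in 2 and Mt2 and Per1 in 1.

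**Figure D1:**
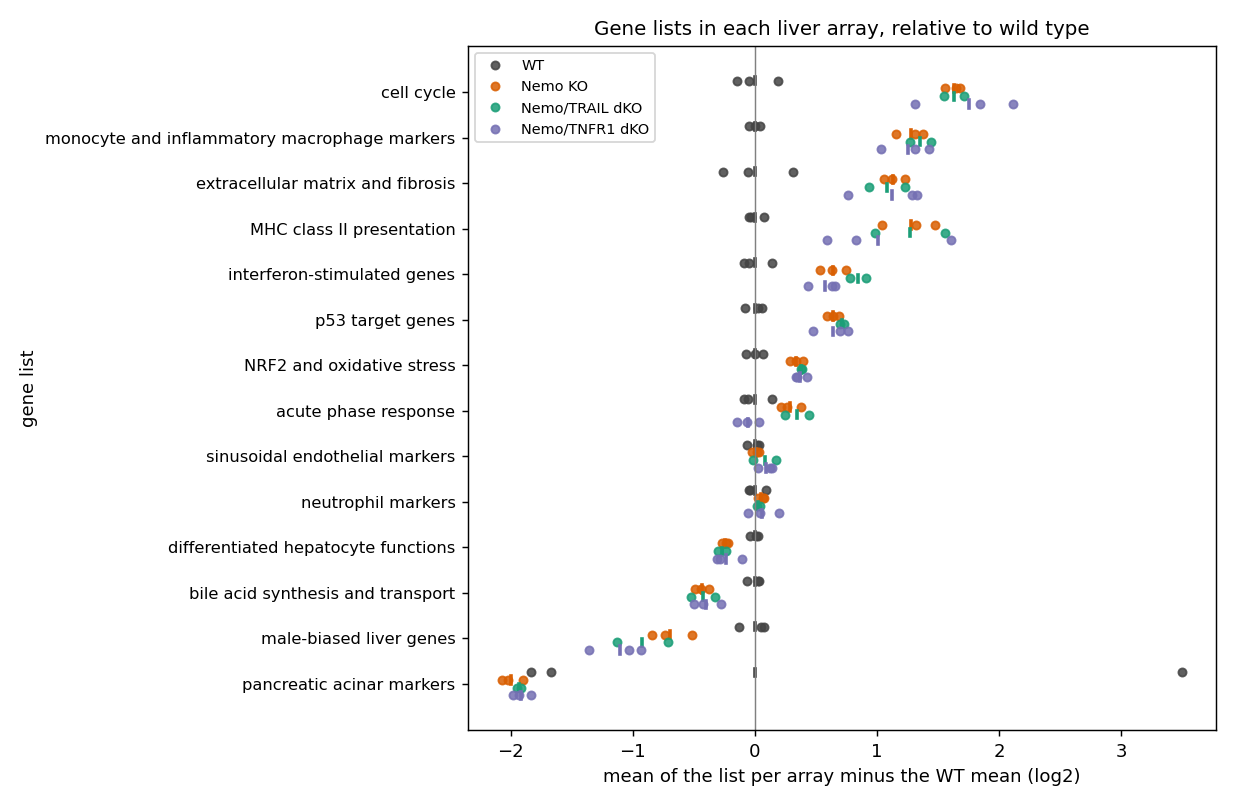
Mean of the measured members of 14 gene lists in each array, as the log2 difference from the WT mean (horizontal axis), for each list (vertical axis); points are arrays, coloured by genotype, and short vertical lines are group means. The cell cycle list lay between 1.31 and 2.11 in the Nemo-deficient arrays and between -0.15 and 0.19 in WT, and the pancreatic acinar list stood at 3.5 in WT replicate 3.

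Of the 37 measured cell cycle genes, 36 rose in Nemo KO and none fell, with a median of 1.70 log2 units, and all 37 rose when adjusted over the list alone. Besides the cyclins, the mitotic kinase Plk1 rose by 2.84 ± 0.29. The list as a set passed (camera adjusted p = 3.46e-32, adjusted p = 0.0936 with an estimated correlation). Among 21 p53 target genes 12 rose and 1 fell (14 and 2 adjusted over the list alone), with a median of 0.69. They included Btg2 (1.75 ± 0.41), the death receptor Tnfrsf10b (1.62 ± 0.18) and Eda2r (1.45 ± 0.25). That list passed at adjusted p = 6.07e-07 (adjusted p = 0.0741 with an estimated correlation). Foetal and tumour-associated hepatocyte genes rose in 8 of 17 cases (12 adjusted over the list alone), with Scd2 at 2.58 ± 0.30 and Igf2bp3 at 1.59 ± 0.10 beside Ly6d. The list passed at adjusted p = 2.97e-07 (adjusted p = 0.0666 with an estimated correlation). Of 15 cholangiocyte and progenitor markers 4 rose (9 adjusted over the list alone), led by Bicc1 (1.55 ± 0.22), Tspan8 (1.11 ± 0.28) and Tnfrsf12a (0.90 ± 0.15). Tspan8 did not pass in 7 of the 11 fits without a single array (adjusted p up to 0.119). As a list these markers passed at adjusted p = 4.26e-05 (adjusted p = 0.3 with an estimated correlation).

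Of 29 extracellular matrix and fibrosis genes 24 rose and none fell (26 adjusted over the list alone), with a median of 1.11, including the proteoglycan Lum (2.40 ± 0.29), Thbs1 (1.94 ± 0.30) and the collagenase Mmp13 (1.85 ± 0.21). The list passed at adjusted p = 3.93e-20 (adjusted p = 0.177 with an estimated correlation). Among 17 hepatic stellate cell markers 9 rose (11 adjusted over the list alone), with the receptors Pdgfrb (1.61 ± 0.20) and Pdgfra (1.41 ± 0.17) and the globin Cygb (1.53 ± 0.14). This list passed with the preset (adjusted p = 1.06e-06) and with an estimated correlation (adjusted p = 0.0435). Of 24 monocyte and inflammatory macrophage markers 22 rose (24 adjusted over the list alone), with a median of 1.12. Beside Gpnmb and Mmp12 they included the lectin receptor Clec7a (2.08 ± 0.19), and the list passed at adjusted p = 1.43e-25 (adjusted p = 0.0741 with an estimated correlation). Of 7 MHC class II genes 6 rose, both over all genes and adjusted over the list alone, with H2-Aa and H2-Ab1 at 1.58 (± 0.33 and ± 0.32) and H2-Eb1 at 1.47 ± 0.34. The list passed at adjusted p = 1.78e-06 (adjusted p = 0.239 with an estimated correlation). Without WT replicate 3, the medians of the cell cycle, matrix and macrophage lists were 1.85, 1.28 and 1.16.

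Of 29 interferon-stimulated genes 15 rose (22 adjusted over the list alone), with a median of 0.59, led by Usp18 (1.8 ± 0.13), Ifi27l2a (1.43 ± 0.23) and Oasl2 (1.23 ± 0.14). Their set test gave adjusted p = 1.05e-13 (adjusted p = 0.104 with an estimated correlation). Among 29 NF-κB target genes 5 rose and 1 fell (8 and 2 adjusted over the list alone), with a median of 0.13. They included the adhesion molecule Vcam1 (2.32 ± 0.21), the chemokine Ccl5 (1.03 ± 0.20) and Gadd45b (0.90 ± 0.24), which lost its call in 9 of the 11 fits without a single array (adjusted p up to 0.15). The list's adjusted p was 0.016 (adjusted p = 0.425 with an estimated correlation), and without Nemo KO replicate 1 it was 0.0663. Of 27 death receptor and apoptosis genes 9 rose and 1 fell (12 and 4 adjusted over the list alone), among them Tnfrsf10b, Casp12 (1.51 ± 0.26) and Mlkl, the executor of necroptosis (1.27 ± 0.15). The list passed at adjusted p = 0.00277 (adjusted p = 0.25 with an estimated correlation). Kupffer cell markers were divided: of 11, Marco (0.90 ± 0.15), Cd5l (0.88 ± 0.17) and a further gene rose, and Cd163 fell (-1.35 ± 0.19), with the same counts adjusted over the list alone. That list passed at adjusted p = 0.0216 (adjusted p = 0.402 with an estimated correlation), and its p rose to at most 0.0839 in the fits without WT replicate 3 or Nemo KO replicate 3. Of 19 T and NK cell markers Ccl5 and Nkg7 (0.72 ± 0.17, lost in 6 of the 11 fits without a single array, adjusted p up to 0.0933) rose, the same number as adjusted over the list alone (list adjusted p = 0.00485, adjusted p = 0.343 with an estimated correlation). Neutrophil markers (1 of 15 rose, none adjusted over the list alone, median 0.03, adjusted p = 0.539) did not pass as a list. Nor did B cell and plasma cell markers (1 of 12 in either case, median -0.07, mean 0.01, adjusted p = 0.947) and sinusoidal endothelial markers (1 of 18, 2 adjusted over the list alone, median -0.04, mean 0.01, adjusted p = 0.635).

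Of 22 male-biased liver genes 9 fell and none rose (14 adjusted over the list alone), with a median of -0.34. They included Hsd3b5, the pheromone carrier Mup21 (-1.31 ± 0.21) and the organic anion transporter Slco1a1 (-1.29 ± 0.21). The list passed at adjusted p = 4.93e-06 (adjusted p = 0.25 with an estimated correlation). Of 19 female-biased genes 1, the receptor Ntrk2, rose (2.59 ± 0.10, adjusted p = 1.75e-05), with the same count adjusted over the list alone. That list passed at adjusted p = 0.016 (adjusted p = 0.425 with an estimated correlation) and not without WT replicate 1 (adjusted p = 0.0654). Of 25 bile acid synthesis and transport genes 7 fell and 1 rose (16 and 3 adjusted over the list alone), with Slco1a1, the nuclear receptor Nr0b2 (-1.12 ± 0.16) and the sterol transporter Abcg8 (-0.86 ± 0.14). Tested as a list, they passed at adjusted p = 0.000695 (adjusted p = 0.262 with an estimated correlation). Among 24 cytochrome P450 genes of drug metabolism 7 fell, among them Cyp2c37 and Cyp2c54 (-1.05 ± 0.19), and 2 rose, among them Cyp2b10 (1.92 ± 0.47), which did not pass in 7 of the 11 fits without a single array (adjusted p up to 0.11). Adjusted over the list alone 12 fell and 2 rose (list adjusted p = 0.00766, adjusted p = 0.451 with an estimated correlation). Of 26 differentiated hepatocyte genes 6 fell and none rose (7 adjusted over the list alone), with Igfals (-1.08 ± 0.13), the histidine lyase Hal (-0.76 ± 0.15) and the coagulation factor F7 (-0.76 ± 0.11). The median of the list was -0.10 (adjusted p = 0.00239, adjusted p = 0.371 with an estimated correlation).

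Of 26 NRF2 and oxidative stress genes 9 rose and none fell (14 adjusted over the list alone), with Srxn1 (1.32 ± 0.13), the glutathione transferase Gstm3 (1.31 ± 0.09) and the haem oxygenase Hmox1 (0.98 ± 0.22). As a set they passed at adjusted p = 1.06e-06 (adjusted p = 0.0819 with an estimated correlation). Among 29 acute phase genes 7 rose and 3 fell (11 and 6 adjusted over the list alone): the metallothionein Mt2 (1.99 ± 0.41) and Orm2, an orosomucoid (1.88 ± 0.18), rose, and Saa3 fell (-1.12 ± 0.10). The list's adjusted p was 0.0314 (adjusted p = 0.402 with an estimated correlation), and it was up to 0.0939 in the fits without WT replicate 1 or Nemo KO replicate 3. All 20 cholesterol synthesis genes were lower, with a median of -0.25, but none passed alone or adjusted over the list alone. The largest difference was that of Tm7sf2 (-0.64 ± 0.21, adjusted p = 0.1), and the list passed at adjusted p = 0.0108 (adjusted p = 0.61 with an estimated correlation) and not without WT replicate 1 (adjusted p = 0.0697). Among 25 genes of lipogenesis and lipid storage 5 rose, with the fatty acid transporter Cd36 (1.92 ± 0.13), the lipase Lpl (1.78 ± 0.20) and Cidec (1.60 ± 0.35). A further 2 fell (7 and 4 adjusted over the list alone, list adjusted p = 0.084). Of 25 fatty acid oxidation and PPARα targets 3 rose, namely Pdk4 (1.28 ± 0.20), Acot2 (0.88 ± 0.17) and Plin2 (0.53 ± 0.10). Adjusted over the list alone 3 rose and 1 fell (list adjusted p = 0.303). The unfolded protein response list had 1 gene of 22 up and 1 down (2 and 2 adjusted over the list alone), with a median of -0.01 and a mean of 0.08 (adjusted p = 0.697). Of 19 circadian clock genes 4 rose and 1 fell, the same as adjusted over the list alone, with Wee1 (1.38 ± 0.32), Bhlhe40 (1.17 ± 0.26) and Per1 (1.15 ± 0.23) among those that rose. The median of that list was -0.18, its mean 0.07 and its set test pointed up (adjusted p = 0.539). All 10 pancreatic acinar markers were lower in Nemo KO, with a median of -1.96 (camera adjusted p = 0.0236, adjusted p = 0.599 with an estimated correlation). None passed alone or adjusted over the list alone, Cpb1 differed by -2.72 ± 1.66 SE (adjusted p = 0.343), and without WT replicate 3 the median was -0.29. Without that array 21 lists passed in place of 22: the pancreatic acinar list kept its call, and the Kupffer cell list lost it. The self-contained test fry, which asks whether the genes of a list move on balance in a single direction, passed 18 of the 29 lists.

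The comparison of Nemo/TNFR1 dKO with Nemo KO asked what the added loss of TNFR1 changes in the Nemo-deficient liver. The acute phase gene Orm2 fell by -1.70 ± 0.18 log2 units (SE, n = 3 and 3, adjusted p = 0.0118), to 9.10 ± 0.30 (SD, n = 3), near its WT level of 8.91 ± 0.08. Clec2h, a C-type lectin gene, fell by -2.00 ± 0.25 SE (adjusted p = 0.0431), and Trem2, a macrophage receptor, rose by 0.74 ± 0.08 SE (adjusted p = 0.0141). Trem2 also stood higher in both Nemo/TRAIL dKO arrays (7.82 and 7.73) than in the Nemo KO arrays (7.28 to 7.45). It is 1 of a group of 8 neighbouring genes on chromosome 17 that is examined below. The other 9 probe sets that passed all carried the names of one family of closely related predicted genes, 4933409K07Rik and its copies, and differed by a median of -2.99 (range -3.30 to -2.61). The family's mean was 6.26 ± 0.11 in Nemo/TNFR1 dKO (SD, n = 3), 9.24 ± 0.14 in Nemo KO (n = 3), 9.25 ± 0.23 in Nemo/TRAIL dKO (n = 2) and 8.72 ± 0.29 in WT (n = 3). In all 12 probe sets passed, 1 higher and 11 lower, and 2440 had an unadjusted p below 0.05, where chance alone would give 1778. On simulated data of this size, 88.1% of 67 probe sets changed 2-fold and 62.7% of those changed 1.5-fold were found, with 10 false calls. As 200 probe sets were changed in those data, the adjustment was milder than with few changes. The shares may thus be too high for this comparison. With only the arrays of these 2 groups in the fit, 9 of the 12 calls were kept, and Trem2, Orm2 and Clec2h had adjusted p of 0.168, 0.175 and 0.175. With a single array left out, they passed in 6, 9 and 4 of 11 fits. Clec2h did not pass with robust moderation (adjusted p = 0.0531), nor did Trem2 and Orm2 with a replicate block (adjusted p = 0.0504 for each).

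Among gene lists, the acute phase list was lower in Nemo/TNFR1 dKO than in Nemo KO. Of its 29 members 23 were lower, with a median of -0.14, 1 fell over all genes (Orm2) and 9 fell adjusted over the list alone (camera adjusted p = 3.36e-11, adjusted p = 0.114 with an estimated correlation). Male-biased genes were also lower, with a median of -0.26 and 6 of 22 falling adjusted over the list alone (adjusted p = 8.98e-10, adjusted p = 0.254 with an estimated correlation). Their member Hsd3b5 differed by -1.78 ± 0.77 SE (adjusted p = 0.72). Unfolded protein response genes were lower in 17 of 22 cases, with a median of -0.16, 4 falling and 1 rising adjusted over the list alone (adjusted p = 1.21e-05, adjusted p = 0.254 with an estimated correlation). Their member Vldlr differed by 1.04 ± 0.30 SE (adjusted p = 0.515). These 3 lists passed with any single array left out. But 8 of the 10 splits of these arrays, the real one included, called at least as many lists as the real one. Foetal hepatocyte genes were lower, with a median of -0.12 and 1 falling adjusted over the list alone (adjusted p = 0.00284, adjusted p = 0.254 with an estimated correlation). Among them Lcn2 differed by -0.92 ± 0.47 SE. That list had adjusted p = 0.0562 without Nemo KO replicate 3. The medians of MHC class II genes (-0.37, H2-Aa -0.44 ± 0.33 SE) and interferon-stimulated genes (-0.07, Oasl1 0.29 ± 0.28 SE) were negative (adjusted p = 0.0323 for each, adjusted p = 0.982 for each with an estimated correlation). Those of female-biased genes (0.36, Cyp2b9 1.91 ± 0.94 SE, adjusted p = 0.0116), PPARα targets (0.11, Cyp4a14 1.53 ± 0.96 SE, adjusted p = 0.00867) and cell cycle genes (0.12, Rrm2 0.68 ± 0.23 SE, adjusted p = 0.0243) were positive, each with adjusted p = 0.982 with an estimated correlation. No member of these last 5 lists passed alone or adjusted over the list alone.

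The calls of these 5 lists ended when a single array was left out. The MHC class II list had adjusted p up to 0.643 without Nemo KO replicate 1 or 3 or Nemo/TNFR1 dKO replicate 1 or 2, and the interferon list up to 0.813 without Nemo KO replicate 2 or 3 or Nemo/TNFR1 dKO replicate 1. Female-biased genes reached 0.0955 without Nemo KO replicate 2 or Nemo/TNFR1 dKO replicate 1, PPARα targets 0.289 without those arrays or Nemo/TNFR1 dKO replicate 2, and cell cycle genes 0.501 without Nemo KO replicate 2 or Nemo/TNFR1 dKO replicate 2 or 3. In all 9 lists passed, 3 up and 6 down. The male-biased, female-biased, PPARα and unfolded protein response lists also passed in the same direction in Nemo/TRAIL dKO against these Nemo KO arrays. Chance deviations of the shared arrays would enter both comparisons. With an estimated correlation camera called 0 of them, and fry called 0. The macrophage list did not pass (median -0.06, 1 of 24 rose over all genes and over the list alone, namely Trem2, adjusted p = 0.301), nor did the matrix list (median -0.02, adjusted p = 0.578), NF-κB targets (median 0, adjusted p = 0.25) or death receptor genes (median -0.03, adjusted p = 0.127). For stellate cell markers (median 0.01) and differentiated hepatocyte genes (median 0.03), neither of which passed (adjusted p = 0.884 and 0.801), the set test pointed down while the median was above 0.

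**Figure D2:**
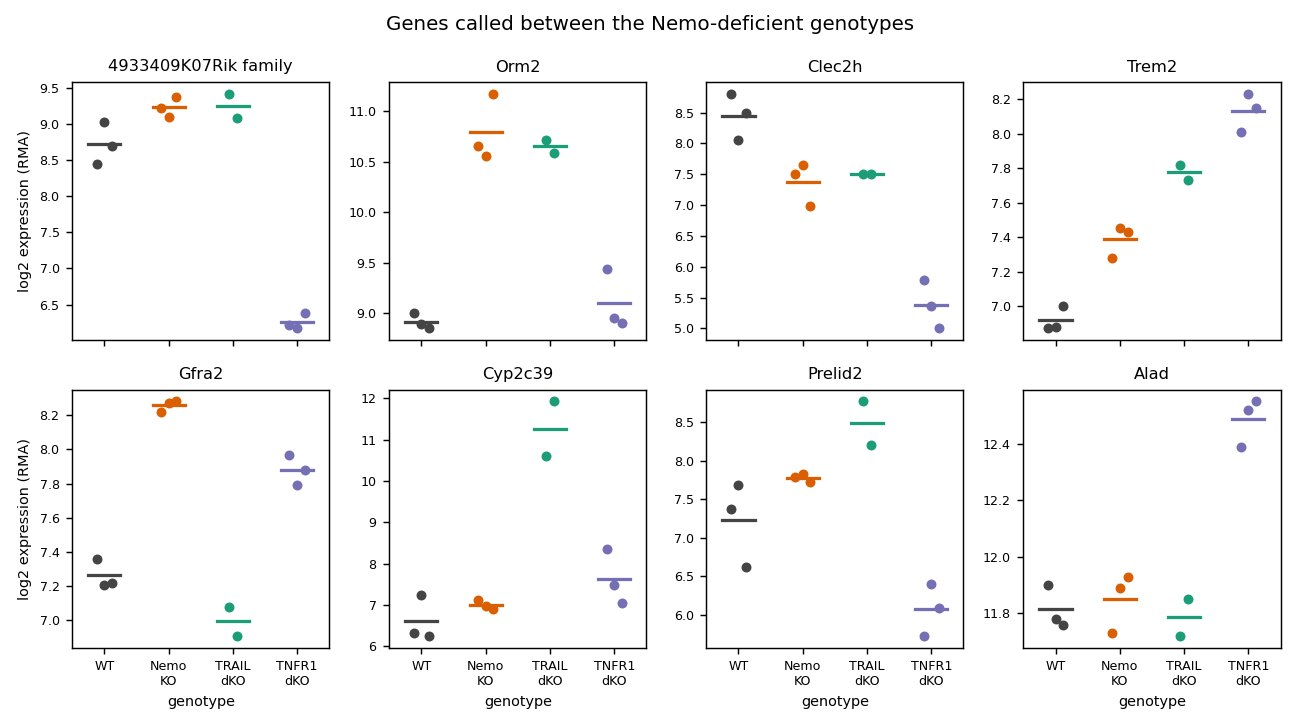
Log2 expression (vertical axes) of genes that passed between Nemo-deficient genotypes, by genotype (horizontal axes); points are arrays, horizontal lines are group means, and the vertical axes differ between panels. Orm2 stood at 9.10 in Nemo/TNFR1 dKO, 10.80 in Nemo KO and 8.91 in WT, and the panel of the 4933409K07Rik family shows the mean of its 9 probe sets.

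The comparison of Nemo/TRAIL dKO with Nemo KO asked what the added loss of TRAIL changes in the Nemo-deficient liver. Gfra2, a receptor for ligands of the GDNF family, fell by -1.26 ± 0.08 log2 units (SE, n = 2 and 3, adjusted p = 0.00231), to 6.99 ± 0.12 from 8.26 ± 0.03 (SD). In the WT arrays it measured 7.21 to 7.36. A probe set with no gene name in the annotation used, 10421186, rose by 2.11 ± 0.18 SE (adjusted p = 0.00994), and no other probe set passed. That does not mean that no other gene differed. Cyp2c39 did not pass, though it measured 10.59 and 11.92 in the Nemo/TRAIL dKO arrays and 6.91 to 7.11 in Nemo KO. At an unadjusted p below 0.05 there were 1436 probe sets, fewer than the 1778 that chance alone would give. On simulated data of this size, 74.6% of 67 probe sets changed 2-fold and 44.8% of those changed 1.5-fold were found, with 4 false calls. Those data held 200 changed probe sets. Where fewer change, the adjustment is stricter, so these shares may overstate what could be found here. Gfra2 had adjusted p = 0.177 with only these 2 groups in the fit and 0.0658 without Nemo/TRAIL dKO replicate 2, and without that array no probe set passed. With only the 2 groups, 10421186 did not pass either, and the 1 probe set that did was another. The count was 1 without Nemo KO replicate 1 or 2, where Gfra2 passed and 10421186 did not. It was 5 without Nemo/TNFR1 dKO replicate 2, an array that enters only through the shared variance.

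As a set, interferon-stimulated genes were higher in Nemo/TRAIL dKO than in Nemo KO in 28 of 29 cases, with a median of 0.17 (camera adjusted p = 6.67e-08, adjusted p = 0.563 with an estimated correlation). Among them Ifit3 differed by 0.57 ± 0.21 SE (adjusted p = 1). Unfolded protein response genes were lower in 18 of 22, with a median of -0.15 (adjusted p = 0.000939, adjusted p = 0.563 with an estimated correlation). Among these Atf3 differed by -0.70 ± 0.34 SE. These 2 lists passed with any single array left out. Female-biased genes were higher (18 of 19, median 0.27, Cyp17a1 1.16 ± 0.61 SE) and male-biased genes lower (18 of 22, median -0.14, Elovl3 -1.55 ± 0.55 SE), with adjusted p of 0.000145 and 0.00109 (adjusted p = 0.563 and 0.704 with an estimated correlation). Without Nemo/TRAIL dKO replicate 2 their adjusted p were at most 0.827 and 0.399, and the male-biased list also failed without Nemo KO replicate 1. Kupffer cell markers (median -0.13, Xlr -0.72 ± 0.30 SE), stellate cell markers (-0.18, Rgs5 -0.38 ± 0.31 SE) and cholesterol synthesis genes (-0.17, Hmgcs1 -0.45 ± 0.24 SE) were lower, with adjusted p of 0.00735, 0.0102 and 0.0419 (adjusted p = 0.671, 0.563 and 0.947 with an estimated correlation). PPARα targets (0.12, Cyp4a14 1.08 ± 1.07 SE) and p53 targets (0.09, Eda2r 0.52 ± 0.28 SE) were higher, with adjusted p of 0.0102 and 0.0408 (adjusted p = 0.848 and 0.671 with an estimated correlation). No member of these 9 lists passed over all genes or adjusted over the list alone. The last 5 lists lost their calls without 1 or more arrays, with adjusted p up to 0.584. Kupffer and stellate genes did so without Nemo KO replicate 3, PPARα genes without Nemo KO replicate 2, and p53 genes without Nemo KO replicate 1 or 2. Stellate, PPARα and p53 genes also did so without Nemo/TRAIL dKO replicate 2, and Kupffer genes without its replicate 1. Cholesterol genes did so without WT replicate 2, Nemo KO replicate 1 or 3 or Nemo/TRAIL dKO replicate 1. The 9 lists were 4 up and 5 down, and camera with an estimated correlation and fry each called 0 of them. Of these, the lists that passed in the same direction in Nemo/TNFR1 dKO share the Nemo KO arrays and are not separate evidence of an effect of each knockout. The macrophage (median 0.02), matrix (-0.08), cell cycle (0.01) and acute phase (0.06) lists did not pass (adjusted p = 0.151, 0.186, 0.793 and 0.0536), and adjusted over the list alone 1 macrophage gene rose.

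The comparison of both double knockouts asked whether the loss of TNFR1 and the loss of TRAIL differ in their effect on the Nemo-deficient liver. The acute phase genes were lower in Nemo/TNFR1 dKO than in Nemo/TRAIL dKO in 28 of 29 cases, with a median of -0.29 log2 units, Orm2 among them (-1.56 ± 0.20 SE, n = 3 and 2, adjusted p = 0.0448). This list passed with the preset correlation (camera adjusted p = 1.15e-20), with an estimated correlation (adjusted p = 0.0204) and by fry (adjusted p = 0.0183), and 1 member fell over all genes and 3 adjusted over the list alone. Without its Orm genes, an exclusion chosen after the data were seen, the 26 other members had the same median of -0.29 and adjusted p = 0.0929 with an estimated correlation. All 29 interferon-stimulated genes were lower, with a median of -0.25 (adjusted p = 1.73e-14, adjusted p = 0.31 with an estimated correlation). Among them Rsad2 differed by -0.63 ± 0.24 SE (adjusted p = 0.932). Both lists passed with any single array left out. Among single genes Gfra2 (0.88 ± 0.08 SE, adjusted p = 0.0057) and Alad, an enzyme of haem synthesis (0.70 ± 0.09 SE, adjusted p = 0.0448), were higher in Nemo/TNFR1 dKO. Lower were the cytochrome P450 Cyp2c39 (-3.63 ± 0.46 SE, adjusted p = 0.0448), Prelid2 (-2.41 ± 0.30 SE, adjusted p = 0.0417), Clec2h (-2.13 ± 0.28 SE, adjusted p = 0.0448) and the 9 probe sets of the 4933409K07Rik family (median -3.0). For Cyp2c39 it was Nemo/TRAIL dKO that stood apart, with 10.59 and 11.92 in its arrays, against 6.25 to 7.25 in WT, 6.91 to 7.11 in Nemo KO and 7.04 to 8.36 in Nemo/TNFR1 dKO.

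In all 17 probe sets passed, 2 higher and 15 lower, among them the unnamed 10344087 (-1.5) and 10421186 (-1.85), and 1788 had an unadjusted p below 0.05 where chance alone would give 1778. The count was 9 with only these 2 groups in the fit and 11 without Nemo/TRAIL dKO replicate 2. With only these groups none of the named genes passed (adjusted p from 0.373 for Prelid2 to 0.709 for Cyp2c39). Gfra2 passed in 10 of the 11 fits without a single array (adjusted p = 0.114 without Nemo/TRAIL dKO replicate 2), Cyp2c39 and Clec2h in 3, Orm2 and Prelid2 in 2 and Alad in 0 of the 11, with adjusted p up to 0.287, 0.332, 0.306, 0.304 and 0.351. These 5 genes did not pass with robust moderation either (adjusted p = 0.0537, 0.0558, 0.0513, 0.0513 and 0.0513), nor with a replicate block (adjusted p = 0.18, 0.0983, 0.179, 0.186 and 0.219), and Alad did not with median centring. The 11 lists that passed were 4 up and 7 down. Beside the acute phase and interferon lists, those down were male-biased genes (median -0.06, Selenbp2 -0.82 ± 0.64 SE), cholangiocyte markers (-0.15, Mmp7 -0.65 ± 0.37 SE), foetal hepatocyte genes (-0.05, Lcn2 -1.17 ± 0.53 SE), macrophage markers (-0.06, Clec7a -0.65 ± 0.21 SE) and MHC class II genes (-0.31, H2-Aa -0.46 ± 0.37 SE). Their adjusted p were 0.00573, 0.0125, 0.0211, 0.0211 and 0.0301, and adjusted p = 0.755, 0.794, 0.512, 0.794 and 0.794 with an estimated correlation. The lists up were Kupffer cell markers (0.23, Xlr 0.83 ± 0.30 SE), cell cycle genes (0.12, Mcm6 0.43 ± 0.23 SE), stellate cell markers (0.14, Angptl6 0.35 ± 0.21 SE) and cholesterol synthesis genes (0.10, Hmgcs1 0.56 ± 0.24 SE). Their adjusted p were 0.0211, 0.0316, 0.0316 and 0.0372, and adjusted p = 0.741, 0.901, 0.388 and 0.901 with an estimated correlation. These 9 lists, with no member that passed over all genes or adjusted over the list alone, lost their calls without 1 or more arrays, with adjusted p up to 0.967. Male-biased, macrophage, cholangiocyte, Kupffer, foetal, MHC class II and cholesterol genes did so without Nemo/TRAIL dKO replicate 1 or Nemo/TNFR1 dKO replicate 1. The foetal and MHC class II lists also did so without Nemo/TNFR1 dKO replicate 2, and the cholesterol list without WT replicate 2 or Nemo/TNFR1 dKO replicate 3. Cell cycle and stellate genes did so without Nemo/TRAIL dKO replicate 2 or Nemo/TNFR1 dKO replicate 2 or 3.

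The comparisons of each double knockout with WT asked how much of the Nemo KO profile each of them shows. Cell cycle genes rose in 37 of 37 cases in Nemo/TNFR1 dKO (median 1.58) and in 35 of 37 in Nemo/TRAIL dKO (median 1.82). Macrophage markers rose in 21 and 20 of 24 (medians 1.06 and 1.13), matrix genes in 24 and 22 of 29 (1.15 and 1.0), interferon-stimulated genes in 14 and 22 of 29 (0.49 and 0.82) and p53 targets in 11 and 10 of 21 (0.66 and 0.73). Adjusted over the list alone, the counts were 37 and 37, 23 and 24, 26 and 24, 20 and 25, and 13 and 13, and 2 and 1 p53 targets fell. With an estimated correlation these lists had adjusted p = 0.0734, 0.0734, 0.16, 0.142 and 0.0734 in Nemo/TNFR1 dKO, and 0.0755, 0.0538, 0.189, 0.0538 and 0.0538 in Nemo/TRAIL dKO. Male-biased genes fell in 14 and 10 of 22 (medians -0.70 and -0.41, 18 and 12 adjusted over the list alone, adjusted p = 0.0752 and 0.189 with an estimated correlation). Bile acid genes fell in 6 and 6 of 25 with 1 and 2 rising (medians -0.30 and -0.46, 11 and 13 falling and 2 and 2 rising adjusted over the list alone, adjusted p = 0.271 and 0.239 with an estimated correlation). The acute phase list passed in Nemo/TRAIL dKO, where 7 members rose and 2 fell (9 and 4 adjusted over the list alone, median 0.06, camera adjusted p = 0.00634, adjusted p = 0.257 with an estimated correlation), but not without its replicate 1 (adjusted p = 0.108). In Nemo/TNFR1 dKO, 4 rose and 7 fell (5 and 8 adjusted over the list alone, median -0.11, adjusted p = 0.185). In Nemo/TNFR1 dKO 3263 probe sets passed (2073 higher, 1190 lower) and 2787 without WT replicate 3. In Nemo/TRAIL dKO 2684 passed (1746 higher, 938 lower) and 2404 without WT replicate 3. In each of these comparisons 23 lists passed, 16 up and 7 down in Nemo/TNFR1 dKO and 17 up and 6 down in Nemo/TRAIL dKO, 18 of them by fry. With an estimated correlation 1 and 0 passed, the 1 being stellate cell markers (adjusted p = 0.0338). Without WT replicate 3, 19 and 21 lists passed.

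The first count dropped to 2157 without WT replicate 2, to 1970 without Nemo/TNFR1 dKO replicate 2, to 1926 without its replicate 3 and to 1831 with only the 2 groups in the fit. The second dropped to 823 without Nemo/TRAIL dKO replicate 1, to 1485 without its replicate 2 and to 1244 with only the 2 groups. Of the 3304 probe sets that passed between Nemo KO and WT, 2332 (70.6%) also passed between Nemo/TNFR1 dKO and WT, 1674 higher and 658 lower in both and 0 in opposite directions. Likewise 2152 (65.1%) also passed between Nemo/TRAIL dKO and WT, 1 of them in the opposite direction. Independent lists would share 126 higher and 38.3 lower probe sets in the first case and 106.1 and 30.2 in the second. These comparisons share the WT arrays, and across probe sets, which are not independent replicates, their log2 differences correlated at 0.83 and 0.85, where simulations with shared controls and no difference gave 0.50 and 0.45. In all 3 comparisons with WT, 1408 probe sets rose and 513 fell. Without WT replicate 3 the shared counts were 2037 and 1928. Against the shared Nemo KO arrays, both double knockouts correlated at 0.48, where the simulations gave 0.45, and limma called 0 probe sets in both.

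A score per array placed each sample between WT (mean 0) and Nemo KO (mean 1), over the probe sets that passed with those 2 groups alone (1920 higher and 870 lower). Nemo/TRAIL dKO scored 0.95 ± 0.11 (SD, n = 2) and Nemo/TNFR1 dKO 0.88 ± 0.19 (SD, n = 3), where Nemo/TNFR1 dKO replicate 1 had 0.66 and the others 0.97 and 1.02. The double knockouts differed by -0.071 (two-sided exact permutation p = 0.8, the smallest possible with 2 and 3 arrays being 0.1), which is less than the spread between replicates. Without Nemo/TNFR1 dKO replicate 1 the difference was 0.039 and without Nemo/TRAIL dKO replicate 1 it was 0.01. Since Nemo KO arrays chose this signature, each double knockout was also compared with Nemo KO on the probe sets that passed between the other double knockout and WT. On the 988 higher and 256 lower probe sets of Nemo/TRAIL dKO, Nemo/TNFR1 dKO scored 1.0 ± 0.17 (SD, n = 3) and differed from Nemo KO by -0.001 (two-sided exact permutation p = 1, smallest possible 0.1). It differed by between -0.055 and 0.097 when WT replicate 1 or 3 or a single Nemo KO or Nemo/TNFR1 dKO array was left out. Without WT replicate 2 or either Nemo/TRAIL dKO array, too few probe sets passed to form this signature. On the 1298 higher and 533 lower probe sets of Nemo/TNFR1 dKO, Nemo/TRAIL dKO scored 1.07 ± 0.05 (SD, n = 2) and differed from Nemo KO by 0.066 (two-sided exact permutation p = 0.5, smallest possible 0.1), and between 0.01 and 0.11 with a single array left out. In designs of this size no such p can pass 0.05, so these values show neither a difference nor its absence.

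**Figure D3:**
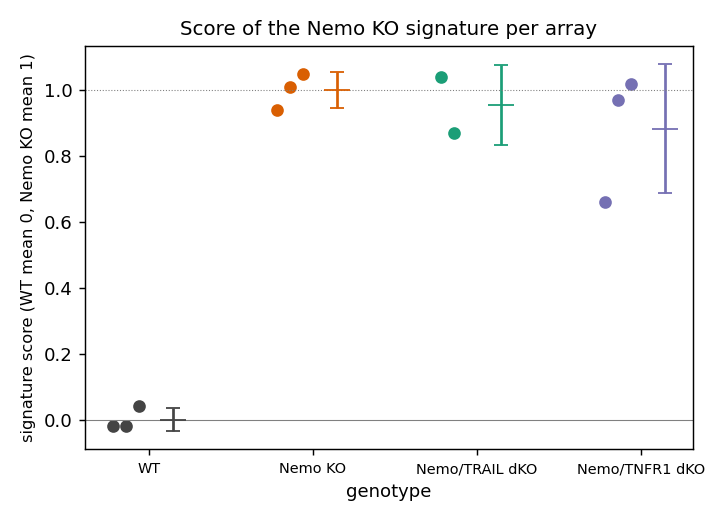
Score of the Nemo KO signature in each array (vertical axis, WT mean 0 and Nemo KO mean 1) by genotype (horizontal axis); points are arrays, and bars show the group mean and its SD (n = 3, 3, 2 and 3). Nemo/TNFR1 dKO replicate 1 scored 0.66, and the other Nemo-deficient arrays lay between 0.87 and 1.05.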

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

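Chosen only after the result was seen were the tests on pancreatic tissue, on the share of hepatocyte RNA, on genes without a small p in Nemo KO, on neighbouring genes and on probes shared within the family, while the tests on the clock, on called genes near the targeted genes and on splits of the arrays were chosen before. A tested difference between the double knockouts drew attention to the following results, all given as Nemo/TNFR1 dKO minus Nemo/TRAIL dKO. The test called 17 probe sets: Gfra2 (0.88), Alad (0.70), Clec2h (-2.13), Orm2 (-1.56), Prelid2 (-2.41), Cyp2c39 (-3.63), the 4933409K07Rik family (9 probe sets, median -3.0) and the unnamed 10344087 (-1.5) and 10421186 (-1.85). The 11 lists were acute phase genes (median -0.29), interferon-stimulated genes (-0.25), MHC class II genes (-0.31), cholangiocyte markers (-0.15), foetal hepatocyte genes (-0.05), macrophage markers (-0.06), male-biased genes (-0.06), Kupffer cell markers (0.23), stellate cell markers (0.14), cell cycle genes (0.12) and cholesterol synthesis genes (0.10). Of these the acute phase list alone also passed with an estimated correlation. The array names carry a code that differs in each double knockout, and if it marks a batch, that batch stays open as an explanation of these differences, confounded with genotype.

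The 10 ways to split 6 arrays into 3 and 3 are too few for a share under 0.05. Each split other than the real one mixes both genotypes in each group. Where the genotypes differ, this widens the spread within groups and lowers the number of called probe sets by construction. The list counts of such splits still carry part of the real difference. Nemo KO against WT called 3304 probe sets and 22 lists, and the highest of the other splits called 21 and 19, so that 1 of the 10 splits, the real one, reached each count. Nemo/TNFR1 dKO against Nemo KO called 12 probe sets and 9 lists, the highest other 3 and 16, and as many were called in 1 and 8 of the 10 splits. The number of lists in this comparison is thus no more than other splits of the same arrays gave. Nemo/TNFR1 dKO against WT called 3263 and 23, the highest other 0 and 18, and 1 split reached each count. The comparisons of Nemo/TRAIL dKO, with its 2 arrays, were not split.

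The rise of macrophage, matrix and cell cycle lists in Nemo KO against WT was weighed against 3 technical explanations. Pancreatic tissue in WT replicate 3 is argued against, since without that array each list kept its call and at least 103.8% of its median. A lower share of hepatocyte RNA as the whole cause is argued against for the macrophage list only, if it would raise sinusoidal endothelial markers alike. The macrophage list lay above them by at least 1.18 log2 units in each Nemo KO array, where that gap ranged over 0.19 between WT arrays. Whether these endothelial markers keep their level per cell in Nemo KO was not tested. For the matrix and cell cycle lists no such gap was computed, so for them this explanation stays open. Time of day cannot be told apart from genotype. Limma called 0 of 4 core clock genes (Arntl, Dbp, Nr1d1 and Per3), but their smallest callable differences were 1.01 to 2.48 log2 units. These 0 calls are thus no evidence against it. Other members of the clock list rose (Per1 by 1.15, Bhlhe40 by 1.17 and Wee1 by 1.38), which need not reflect the clock. Their calls were lost in 1, 4 and 5 of 11 fits without a single array, and the clock list, with a negative median, did not pass. The loss of Nemo, the difference in the design, stays open as a candidate explanation.

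The genes that differed most in Nemo/TNFR1 dKO against Nemo KO were examined for their distance from Tnfrsf1a and from each other. Within 10 Mb of Tnfrsf1a 1 of 266 genes was called (Clec2h), against 2 of 19586 others (two-sided Fisher exact p = 0.0397). The exact p was 0.0246 within 5 Mb and 0.0565 within 20 Mb. A strain variant carried with the targeted locus would give this. But genes there were also called more often in Nemo KO against WT (exact p = 0.0254). At an unadjusted p below 0.01, a threshold chosen afterwards, there were 12 of 266 against 297 of 19586 (exact p = 0.000994). Within 5 Mb there were 11 of 164 (exact p = 5.41e-05), and 2 of 164 in Nemo/TRAIL dKO against Nemo KO (exact p = 0.322). Within this window there were 10 of 164 between the double knockouts (exact p = 2.98e-06) and 40 of 164 in Nemo KO against WT (exact p = 0.00785). Among genes without a small p in Nemo KO against WT the exact p was 0.103 near Tnfrsf1a (4 of 174). Near Tnfsf10 it was 1 (0 of 61, where the share near Tnfrsf1a would give 1.4 genes). Between the double knockouts it was 0.00757 near Tnfrsf1a (5 of 174). A strain variant thus stays open, and few genes in this last set had a small p. The 47 genes with the smallest p formed 34 pairs of neighbours (random mean 10.8, as many in 1 of 10000 random sets, and 15 pairs among as many genes of Nemo KO against WT), with 18 pairs without Nemo KO replicate 3 (as many in 504 of 10000 random sets), 19 without Nemo/TNFR1 dKO replicate 1 or 2, 22 without its replicate 3 and 51 without WT replicate 2. Stretches of DNA of another strain kept by one colony and an effect of TNFR1 stay open, since 28 of the pairs lie within 1 group on chromosome 17. Its 8 genes are Tnfrsf21, Adgrf1, Enpp4, Nfkbie, Tmem63b, Slc22a7, Mea1 and Trem2. Their sign in Nemo/TRAIL dKO against the same Nemo KO arrays decides nothing, being the same in 8 of 8 but also in 33 of the 39 other genes. Gene families were judged only by symbols that share their first 3 letters. By this measure they are not the source of most pairs, since 32 joined genes that differ in these letters (random mean 10.4). But most pairs come from the 1 group on chromosome 17. Symbols also cannot show whether neighbours with unlike names respond together. Without any single array at least 18 such pairs were left (as many in 372 of 10000 random sets). In Nemo/TRAIL dKO against Nemo KO, 15 genes formed 3 pairs of neighbours (as many in 870 of 10000 random sets). A group of 3 on chromosome 14 holds Entpd4, Gfra2 and Cysltr2. Between the double knockouts 26 genes formed 9 pairs (as many in 127 of 10000). Neither count was repeated with an array left out, so a strain variant stays open there too.

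Of the 12 probe sets called in Nemo/TNFR1 dKO against Nemo KO, 9 carry the names of the 4933409K07Rik family. Probes shared between near-identical copies are a candidate explanation for their number, since their deviations within groups correlated with a median of 0.924, where random sets gave medians from -0.2 to 0.28. The 9 calls may thus stand for fewer independent ones. Why the family was lower in Nemo/TNFR1 dKO stays open, with the loss of TNFR1 and a variant of the colony both untested.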

How the results depend on the processing

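Chosen only after the data were seen were the exclusion of probe sets below the first named ID, of the Orm genes and, for overlaps, of WT replicate 3. The cause of the changes below was not tested, except that stricter thresholds and fewer probe sets or arrays change counts by construction. Where 1 array was left of Nemo/TRAIL dKO, it is assumed to vary like the other groups. Signal over background limits dim genes, but the filters on mean signal do not show this. Nemo/TRAIL dKO against Nemo KO had 1 call in place of 2 above the 25th percentile and 2 calls above the median. Of the values of named called genes, 801 kept direction and call with an array left out and 145 kept direction only, and with other settings 1034 and 78, while none reversed.

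A fold of at least 1.5 left 1680, 1625 and 1617 calls against WT in Nemo KO, Nemo/TNFR1 dKO and Nemo/TRAIL dKO in place of 3304, 3263 and 2684, and an adjusted p below 0.01 left 1416, 1411 and 1018. The stricter p left 11 of 17 calls between the double knockouts and turned the independent Nemo/TNFR1 dKO signature from -0.001 to 0.066. With only the 2 groups in the fit the double knockouts had 1831 and 1244 calls against WT and 9 against each other. Nemo/TRAIL dKO against Nemo KO then had 1, which was neither of the calls of the main fit. Single-symbol probe sets gave 4 calls for Nemo/TNFR1 dKO against Nemo KO and 6 between the double knockouts. Without probe sets below the first named ID, Nemo/TRAIL dKO against Nemo KO had 4 calls. Under median centring, calls against WT were higher in 56.4%, 55.6% and 57.9% of cases in place of 65.4%, 63.5% and 65.1%.

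With an estimated correlation camera called 1, 1 and 0 lists against WT in Nemo KO, Nemo/TNFR1 dKO and Nemo/TRAIL dKO, 0 in either double knockout against Nemo KO and 1 between them. By fry the last 3 counts were 0, 0 and 1. The preset gave 22, 23, 23, 9, 9 and 11. With a replicate block the calls were 2781, 11, 3, 2771, 2261 and 12 (Nemo KO against WT, Nemo/TNFR1 dKO and Nemo/TRAIL dKO against Nemo KO, then against WT, and against each other), but replicate numbers do not appear to pair samples, since 0 of 11 arrays were closest to an array of the same number in another group.

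Near Tnfrsf1a, the share called in Nemo/TNFR1 dKO against Nemo KO was 0.262% within 20 Mb (exact p = 0.0565). Against WT it was 19.5% within 5 Mb (exact p = 0.00551) and 16.8% within 20 Mb (exact p = 0.00681), and between the double knockouts 0.61% within 5 Mb (exact p = 0.0486). Near Tnfsf10, it was 3.12% within 5 Mb (exact p = 0.249), now below other genes, and 16.1% within 20 Mb (exact p = 0.0263) in Nemo/TRAIL dKO against WT.

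With a single array left out, calls ranged from 1933 to 3549 in Nemo KO against WT (1979 without Nemo KO replicate 2), from 1926 to 3342 in Nemo/TNFR1 dKO against WT, from 823 to 2884 in Nemo/TRAIL dKO against WT, from 0 to 5 in Nemo/TRAIL dKO against Nemo KO and from 11 to 17 between the double knockouts. The lowest counts came without Nemo KO replicate 3, Nemo/TNFR1 dKO replicate 3, Nemo/TRAIL dKO replicate 1, and for the last 2 Nemo/TRAIL dKO replicate 2. Lists ranged from 5 to 13 in Nemo/TNFR1 dKO against Nemo KO and from 6 to 14 between the double knockouts.

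Signs turned in these leave-one-out ranges. In Nemo/TNFR1 dKO against Nemo KO they were cell cycle -0.052 to 0.317, interferon -0.145 to 0.006 and Tnfsf10 -0.014 to 0.286, and in Nemo/TRAIL dKO against Nemo KO PPARα targets -0.023 to 0.225 (-0.061 to 0.33 against WT). Between the double knockouts they were cell cycle -0.045 to 0.329, cholangiocyte -0.35 to 0.017, male-biased -0.284 to 0.024, macrophage -0.192 to 0.038, MHC class II -0.694 to 0.047, cholesterol -0.039 to 0.37, Angptl6 -0.014 to 0.713, Ikbkg -0.089 to 0.007 and the Nemo signature -0.152 to 0.039. The independent Nemo/TNFR1 dKO signature ranged from -0.055 to 0.097, and could not be formed without WT replicate 2 or either Nemo/TRAIL dKO array, since probe sets did not pass in both directions. That of Nemo/TRAIL dKO kept its sign (0.01 to 0.11).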

Other observations

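The list means of B cell, neutrophil and sinusoidal endothelial markers stayed close to their WT means in the Nemo-deficient arrays. The mean of the B cell list lay between -0.044 and 0.084 log2 units in these arrays, that of the neutrophil list between -0.057 and 0.199 and that of the sinusoidal endothelial list between -0.023 and 0.178. The last list exceeded its WT range (-0.06 to 0.039) in Nemo/TRAIL dKO replicate 2 (0.178) and Nemo/TNFR1 dKO replicates 1 and 2 (0.14 and 0.123). B cell and neutrophil means were low in all arrays (5.871 to 6.005 and 5.269 to 5.525). Array medians were 6.26 to 6.32, so low signal may hide changes in these cells. Nemo/TNFR1 dKO replicate 1 had the lowest Nemo signature score (0.66) and the lowest cell cycle mean (1.31) of the Nemo-deficient arrays. On the first principal component, which held 37.1% of the variance, it lay at 2.5, between WT (-48.2 to -42.8) and the other Nemo-deficient arrays (13.4 to 24.9).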
